A study of Rattus norvegicus with 8 samples.

How the data were processed

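Rat airway epithelium was profiled by droplet single-cell RNA sequencing in 8 libraries, made with the 10x Genomics v2 workflow and sequenced on the HiSeq 4000 instrument, per the labels. Each library stood alone in its group: native trachea, expanded basal cells at passages 1, 3 and 6 (P1, P3 and P6), and cells differentiated at an air-liquid interface, in organoids, in an engineered trachea and in an engineered lung. For the replicated comparison the 3 passages formed the expanded state and the 4 platforms the differentiated state. The labels do not say that the libraries come from separate animals or cultures, so p-values measure only the spread between these samples.

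The deposited matrices held raw UMI counts per gene and cell, without normalization. The authors' identity files gave UMI and gene counts per cell, which equalled the column sums of the matrices once matched by barcode. They also gave the mitochondrial share of each cell's UMIs, deposited as a fraction between 0 and 1. Cells had been filtered before deposit, since the 3 expanded libraries held no cell with 4500 or more genes or with 5% or more mitochondrial UMIs, while the other libraries held both. The aligner, the counting tool and the genome build are not given in the sources used here. Gene names were used as the files gave them, and a gene absent from a library's gene list was counted as 0 there. The files listed 21066 genes in any library and 15422 in all 8.

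Cell types of the native and differentiated libraries were the authors' names. Names of the deposited broad annotation column were put into the basal, secretory or ciliated class by the word in the name, and other names stayed classes of their own. Native cells named Keratinocyte counted as basal, following 1 of the deposited annotation columns. They shared the leading genes Upk3bl1, Mal, Calcb and Serpinb2 with the engineered trachea subset named Intermediate, which counted as secretory. Similar cells may thus sit in different classes of the libraries compared. Identity files of the expanded libraries held only cluster numbers, and these deposited clusters were named with "-like" from the fixed marker genes, in place of the new clustering that had been planned for this case. A cluster needed at least 3 detected markers at 50 CPM. It left the basal-like class when 2 or more of its 10 leading genes, and more than those of the basal list, marked another type or a mesenchymal transition. That naming rule was set after the clusters had been seen. Cycling clusters stayed in the basal class. Doublets were scored with Scrublet as implemented in scanpy 1.11.5, which called between 0.01% and 0.9% of cells per library. With 0.12% of P1 cells and 0.01% of P3 cells called, the caller had not worked there, and no cell was removed in the main analysis.

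UMIs were summed over all cells of a library, or over a cell class, and divided by the library or class total and scaled to CPM, the field's unit of UMIs relative to a fixed total. Expanded and differentiated libraries were compared with the edgeR 4.0.16 quasi-likelihood test (robust, TMM scaling, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists with at least 5 tested members were tested with camera from limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. Comparisons between single libraries have no replicate check. For these, ratios of (CPM + 5) are described, with an exact conditional binomial interval at 95%, and a list's median is placed among 10000 random lists of the same size matched on mean expression. A list is said to stand apart when its median lay at or below the 2.5th or at or above the 97.5th percentile; members entered with a mean of at least 5 CPM. Because totals differ in composition, the median over all genes is given for comparisons where another scaling moves it. Shares of cells carry exact Clopper-Pearson intervals. All intervals and floors cover counting error only. A ratio against 0 UMIs is a lower bound that uses 3 UMIs in place of 0.

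Gene lists, cell type markers, the tests, the main alternatives and the rule for naming genes were fixed before the data were examined. The 34 lists held 489 genes, of which 455 matched the files, 5 of them through an older or newer symbol. Krt6a, Krt6b, Krt16 and Pthlh of the keratinocyte stress list had no match, so its stress keratins other than Krt17 were not measured. The squamous list lacked Krt6a, Krt6b, Krt16, Krt1, Ivl and Lor. Besides list members, the rule took the 12 largest changes in each direction among genes with an adjusted p under 0.05, at least 50 CPM in the higher state and no overlap between states. In single comparisons it took the 10 largest log2 ratios in each direction, and between platforms the 5 largest, at 50 or more CPM and UMIs. Unnamed gene models, ribosomal and mitochondrial genes outside the lists were passed over.

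The tests were checked on simulated data with 200 changed genes, fewer than were called in the data, so the recovered shares do not describe the reach of the real comparison. In the simulation of all cells, the edgeR test recovered 0% of genes changed by a log2 of 1 or 2 and 32.5% of those changed by 3, with 2 unchanged genes called, 13.3% of its calls and above the threshold of 0.05. For the basal class it recovered 0%, 28.7% and 65.0%, with 1 unchanged gene called. Intervals of ratios covered the simulated value for 95.2% of genes in the comparison of P6 with P1, and for 95.4% in that of the air-liquid interface with native basal cells. Those counts were drawn from a Poisson distribution, the model behind the interval, so coverage near 95% was built in. It does not show that the intervals cover variation between cells. Alternatives covered the tool, scaling, gene filters, cell filters, doublets, annotation, pseudocounts and leaving out each library. The other native annotation was applied to cell shares only. Ratios, list medians and correlations were not computed again with it. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the other steps, and DESeq2 1.42.0 for 1 alternative.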

Results

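The series followed rat tracheal basal cells, the stem cells of the airway surface, through expansion in culture and differentiation. Epithelium scraped from native trachea gave 640 cells. Cells from such scrapings had been grown on collagen-coated plastic in a pharmacological expansion medium and were sequenced at P1 (7557 cells), P3 (10955 cells) and P6 (2234 cells). Expanded cells were then differentiated, in the same airway differentiation medium, at an air-liquid interface (1566 cells), in organoids (2387 cells), in an engineered trachea (2613 cells) and in an engineered lung (778 cells). Total depth ranged from 13587569 UMIs in native trachea and 15294292 in the engineered lung to 70307037 at P3 and 70708324 at P1. P6 held 46292994 UMIs, the air-liquid interface 28696221, the organoid 35183533 and the engineered trachea 46996419. Median UMIs per cell were lowest at P3 (5697) and highest at P6 (20948). Every group was a single library, medium changed together with state, and cells were dissociated by a protocol of each platform's own, so these factors cannot be separated from expansion or platform.

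Which cell types each condition held was asked first. Native trachea held 49.7% basal (95% exact interval 45.7 to 53.6), 27.2% secretory (23.8 to 30.8), 13.8% tuft (11.2 to 16.7) and 9.38% ciliated cells (7.23 to 11.9). Basal-like clusters made up 68.4% of P1 cells, 83.1% of P3 cells and 95.2% of P6 cells. Each held 9 or 10 basal markers at 50 CPM, but the squamous-like P3 cluster held 10 too. The 10 leading genes of every basal-like P3 cluster, and of clusters BCP1_2 at P1 and BCP6_1 at P6, held no basal marker. At P1 a secretory-like cluster led by Scgb3a1 and Bpifa1 took 28.9% of cells, and a cluster of 2.75% led by matrix and mesenchymal transition genes stayed unnamed. Squamous-like clusters took 16.9% of P3 cells (16.2 to 17.6) and 4.79% of P6 cells (3.94 to 5.76). No expanded cluster was ciliated-like or tuft-like. Classes were given to whole clusters, the smallest of which held 208 cells at P1, 1312 at P3 and 107 at P6, so fewer ciliated or tuft cells inside a larger cluster would not be counted. Secretory cells formed the largest class of the air-liquid interface (51.8%, 49.3 to 54.3), of the engineered trachea (69.0%, 67.2 to 70.8) and of the engineered lung (44.3%, 40.8 to 47.9). In the organoid, basal cells took 50.4% (48.3 to 52.4) and secretory cells 47.6% (45.6 to 49.7). Multiciliated cells made up 8.69% of the engineered trachea (7.64 to 9.83), 3.38% of the air-liquid interface culture (2.55 to 4.40) and 1.51% of the organoid (1.06 to 2.08). No engineered lung cluster was named ciliated or tuft, the smallest cluster there holding 36 cells. A class named for Hopx, a gene of the alveolar list, took 20.7% of engineered lung cells (17.9 to 23.7). Sprr1a, of the squamous list, was also among the leading genes of that class, and Hopx led the squamous-like cluster of P6. Tuft cells stayed at 0.70% or below on every platform, against 13.8% in native trachea. Limits on genes per cell differed between the expanded and the other libraries and can move such shares. Counting native cells named Keratinocyte as secretory gave 43.0% basal and 33.9% secretory cells. The engineered trachea subset named Intermediate, which shared leading genes with those cells, was counted as secretory and made up 19.2% of its library.

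**Figure D1:**
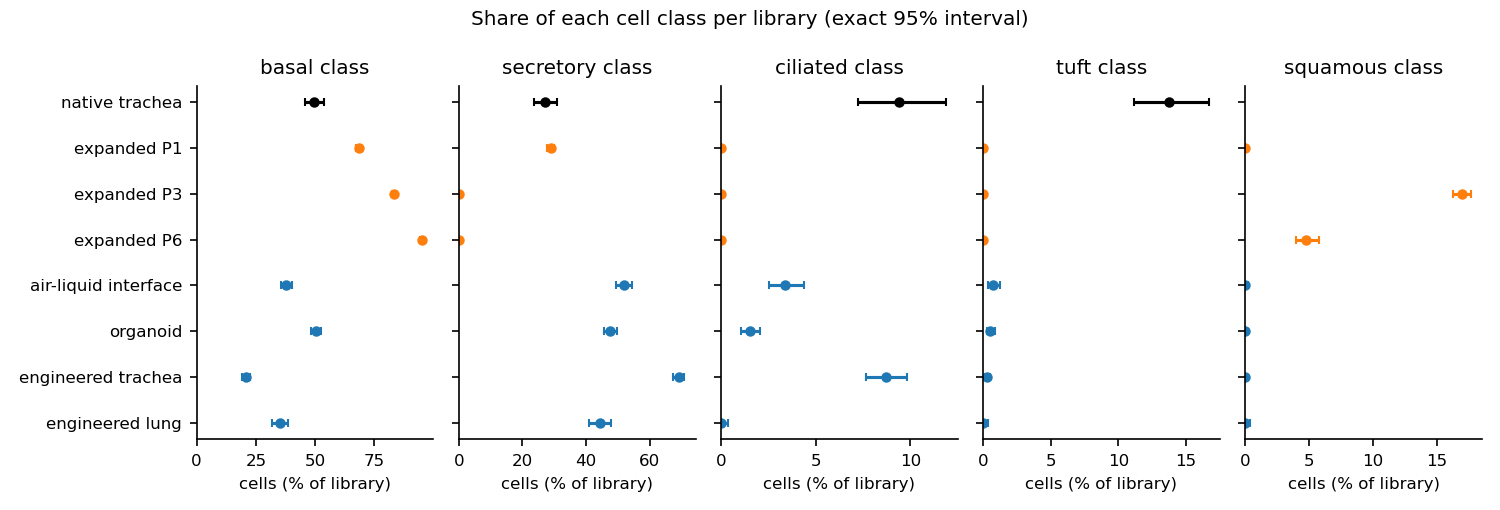
Share of cells in each class (x axis, % of the library) for the 8 libraries (y axis), with exact 95% intervals that cover counting error, not the naming of clusters; native is black, expanded orange and differentiated blue. Ciliated cells reach 9.38% in native trachea and 8.69% in the engineered trachea, and squamous-like cells 16.9% at P3.

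Expanded and differentiated cells were compared next, over all cells, with 3 libraries against 4. Members of the airway secretory, ciliary and ion and water transport lists rose in the differentiated libraries. Members of the cell division, ribosomal protein, respiratory chain and squamous lists fell. With an estimated correlation camera called 0 of the lists tested. The ciliary, cell division and squamous lists also failed fry (adjusted p = 0.0914, 0.102 and 0.0738). Of 12 tested secretory genes 9 rose (11 adjusted over the list alone), with a median log2 fold change of 5.60 (camera adjusted p = 1.52e-07; adjusted p = 0.295 with an estimated correlation). Among them Muc1, a cell-surface mucin, went from 0.26 ± 0.22 CPM (SD, n = 3) to 16.4 ± 7.24 CPM (SD, n = 4), a log2 fold change of 5.55 (SE 0.654, edgeR quasi-likelihood adjusted p = 0.00897). Spdef, a transcription factor of mucous cells, had a log2 fold change of 4.14 (adjusted p = 0.012). The club cell secretoglobin Scgb1a1 averaged 36.3 ± 62.3 CPM in the expanded and 13042 ± 12483 CPM in the differentiated libraries (adjusted p = 0.0473), a call that ended without the air-liquid interface, the engineered trachea, the organoid, P3 or P6. Scgb3a2 had 3 UMIs over all expanded libraries and 12040 over the differentiated ones, a ratio of 5958 in pooled CPM (95% interval 2038 to 28895). Of 19 ciliary genes 10 rose (17 adjusted over the list alone), with a median log2 fold change of 4.04 (camera adjusted p = 1.23e-05; adjusted p = 0.436 with an estimated correlation). Dynlrb2, a dynein light chain, went from 0.15 ± 0.07 to 110 ± 154 CPM (adjusted p = 0.024), and Dnah9, an axonemal dynein heavy chain, from 0.51 ± 0.19 to 14.7 ± 15.6 CPM (adjusted p = 0.0238), and both calls ended without any of the 3 passages. In the deuterosomal list, genes of cells that are amplifying centrioles, 3 of 5 rose. Ccno among them had 0 UMIs in the expanded libraries and was at least 392-fold higher in the differentiated ones.

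Ion and water transport genes rose in 8 of 15 cases (9 adjusted over the list alone), with a median log2 fold change of 3.24 (camera adjusted p = 2.88e-05; adjusted p = 0.229 with an estimated correlation). The epithelial sodium channel subunit Scnn1a went from 10.7 ± 4.86 to 145 ± 52.2 CPM (log2 fold change 3.24, SE 0.496, adjusted p = 0.0107). Atp1b1, a subunit of the sodium pump, went from 16.6 ± 16.4 to 489 ± 134 CPM (4.44, SE 0.777, adjusted p = 0.0137). Feedback genes of BMP and TGF-beta signalling rose in 5 of 11 cases (camera adjusted p = 0.00153; adjusted p = 0.387 with an estimated correlation). Smad7, an inhibitory Smad, went from 2.52 ± 0.78 to 38.9 ± 13.6 CPM (3.43, SE 0.418, adjusted p = 0.00897), and Pmepa1, another inhibitor of TGF-beta signalling, from 0.89 ± 0.72 to 92.6 ± 65.5 CPM (6.21, SE 0.972, adjusted p = 0.0113). Of 20 genes of xenobiotic metabolism 6 rose and 1 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.00153; adjusted p = 0.387 with an estimated correlation). The flavin monooxygenase Fmo2 had a log2 fold change of 10.06 (SE 1.18, adjusted p = 0.00897), and the carboxylesterase Ces1d one of 5.02 (adjusted p = 0.0103), while Cyp2s1 fell. Retinoid genes split, with 6 of 12 risen and 1 fallen (7 and 1 adjusted over the list alone; camera adjusted p = 0.0135; adjusted p = 0.295 with an estimated correlation). Rarres1, named for its induction by retinoic acid, went from 0.25 ± 0.14 to 475 ± 442 CPM (10.40, SE 1.08, adjusted p = 0.00897), and the retinoic acid carrier Crabp2 fell from 146 ± 133 to 8.95 ± 5.19 CPM (-4.77, adjusted p = 0.0191). Among 16 neutrophil-recruiting and antimicrobial genes 3 rose (6 adjusted over the list alone; camera adjusted p = 0.00994; adjusted p = 0.387 with an estimated correlation). They were Nos2, the immunoglobulin transporter Pigr (8.12, adjusted p = 0.0126) and the whey acidic protein gene Wfdc2, which went from 95.4 ± 66.9 to 4934 ± 3056 CPM (5.16, adjusted p = 0.0129). Interferon response genes rose in 4 of 18 cases, Irf1 and Ifit2 among them (camera adjusted p = 0.0138; adjusted p = 0.295 with an estimated correlation). In the alveolar list 4 of 9 genes rose, including the surfactant collectin Sftpd (0.88 ± 1.49 to 509 ± 381 CPM, adjusted p = 0.0212; camera adjusted p = 0.0291; adjusted p = 0.315 with an estimated correlation). The tuft list as a whole lay higher, with a median log2 fold change of 1.41 (camera adjusted p = 0.0311, and 0.387 with an estimated correlation). However, 0 of its 9 tested members passed, also when adjusted over the list alone. Genes outside the lists that rose included Chst9, a sulfotransferase (0.41 ± 0.41 to 325 ± 317 CPM, adjusted p = 0.00901), Ly6al, the mucus-associated gene Clca1, Igfbp5, Akr1cl and Gp2.

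Cell division genes fell in 14 of 28 cases (26 adjusted over the list alone), with a median log2 fold change of -2.78 (camera adjusted p = 1.23e-05; adjusted p = 0.456 with an estimated correlation). With library totals as the only scaling 7 of the 28 passed, at a median of -2.43. The tubulin gene Tubb5 went from 780 ± 280 to 178 ± 67.6 CPM (-2.68, SE 0.33, adjusted p = 0.00897), Stmn1 from 289 ± 293 to 43.9 ± 18.9 CPM (-3.13, adjusted p = 0.0143) and Rrm2, of nucleotide synthesis, from 13.7 ± 17.0 to 0.53 ± 0.20 CPM (-5.06, adjusted p = 0.0121). All 13 ribosomal protein genes fell, with a median of -1.48 (camera adjusted p = 1.4e-05; adjusted p = 0.387 with an estimated correlation). Their adjusted p reached 0.0499 for Rpl10, and with library totals as the only scaling 4 of the 13 passed, at a median of -0.86. Respiratory chain genes fell in 7 of 12 cases (11 adjusted over the list alone; median -1.01, camera adjusted p = 6.27e-05; adjusted p = 0.295 with an estimated correlation), led by Uqcrc1 (254 ± 30.6 to 101 ± 21.8 CPM, adjusted p = 0.00897). With library totals alone 1 passed. Squamous genes fell in 5 of 12 cases (6 adjusted over the list alone; camera adjusted p = 0.0067; adjusted p = 0.387 with an estimated correlation). The transglutaminase Tgm1 went from 154 ± 77.5 to 16.9 ± 10.8 CPM (-3.65, SE 0.603, adjusted p = 0.0122), and the cornified envelope gene Cnfn had 26371 UMIs in the expanded libraries and 1 in the differentiated ones (ratio 17763, 3188 to 701645). Cnfn stood at 1.39 CPM at P1, 359 CPM at P3 and 22.5 CPM at P6, and at 1724 CPM in the squamous-like cells of P3. With library totals alone 3 squamous genes passed, at a median of -2.06. Cystatin and serpin genes fell in 4 of 8 cases (4 adjusted over the list alone; median -3.26, camera adjusted p = 0.00187; adjusted p = 0.387 with an estimated correlation), among them the protease inhibitor Cst6 (1649 ± 637 to 145 ± 74.6 CPM, -4.08, SE 0.521, adjusted p = 0.00897). Basal markers fell in 4 of 11 cases (median -1.23, camera adjusted p = 0.0251; adjusted p = 0.456 with an estimated correlation). Over the list alone, 7 fell and 1 rose. With library totals alone 3 basal markers fell and 1 rose, at a median of -0.60. The keratin Krt17 went from 10483 ± 8901 to 526 ± 329 CPM (-4.91, SE 0.856, adjusted p = 0.0136), and Krt5 from 2485 ± 1987 to 537 ± 220 CPM (-2.88, adjusted p = 0.025). Cholesterol synthesis genes fell in 3 of 15 cases (4 adjusted over the list alone; camera adjusted p = 0.00929; adjusted p = 0.476 with an estimated correlation), Fdps, Fdft1 and Msmo1, and library totals alone ended those calls at a median of -0.48. Among further genes that fell were Fgfbp1, a carrier of fibroblast growth factors (1261 ± 482 to 148 ± 74.4 CPM, -3.61, adjusted p = 0.00897), Igfbp2, Fam25a, Cdkn3, Ifitm10, Cdc42ep5 and Dmkn.

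The remaining 12 lists had camera adjusted p values from 0.0552 to 0.879, though single members passed. The glycolytic enzyme Eno1 fell (1404 ± 378 to 383 ± 165 CPM, -2.45, adjusted p = 0.00945), as did the p53 target Phlda3 (429 ± 73.7 to 131 ± 23.8 CPM, -2.33, adjusted p = 0.00899). In the Notch list, Notch2 and Mfng rose and the ligands Jag1 and Dll4 fell, but neither fall passed with library totals alone or with the cell limits of the expanded libraries. The integrin subunits Itgav and Itgb6, partners that activate latent TGF-beta, rose. Fosb (3.21, adjusted p = 0.0163) and Egr1 (1.98, adjusted p = 0.0359), immediate early genes that tissue dissociation induces, rose too. Among all genes, 3312 of 15883 tested passed the edgeR test, 1391 risen and 1921 fallen. States did not overlap for 5472 of all tested genes, where chance gives 5.7%, and the called genes held 2289 of these. With library totals as the only scaling, the median log2 fold change of all genes shifted by 0.548 and the split became 2636 risen and 463 fallen. The count was 5012 with DESeq2, and it was 490 without P3 and 796 once the cell limits of the expanded libraries were applied everywhere. Under those limits 4 secretory and 2 cell division genes passed, while the list medians of 5.42 and -2.92 stayed near those of all deposited cells. Ciliary genes passed in 4 cases at a smaller median of 2.38, and the ribosomal protein genes no longer passed, at -0.98. Of 132 list members called, 25 passed with each library left out in turn, and leaving out P3 ended the most calls, 104. Fold changes rest on TMM scaling, while the CPM means do not.

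**Figure D2:**
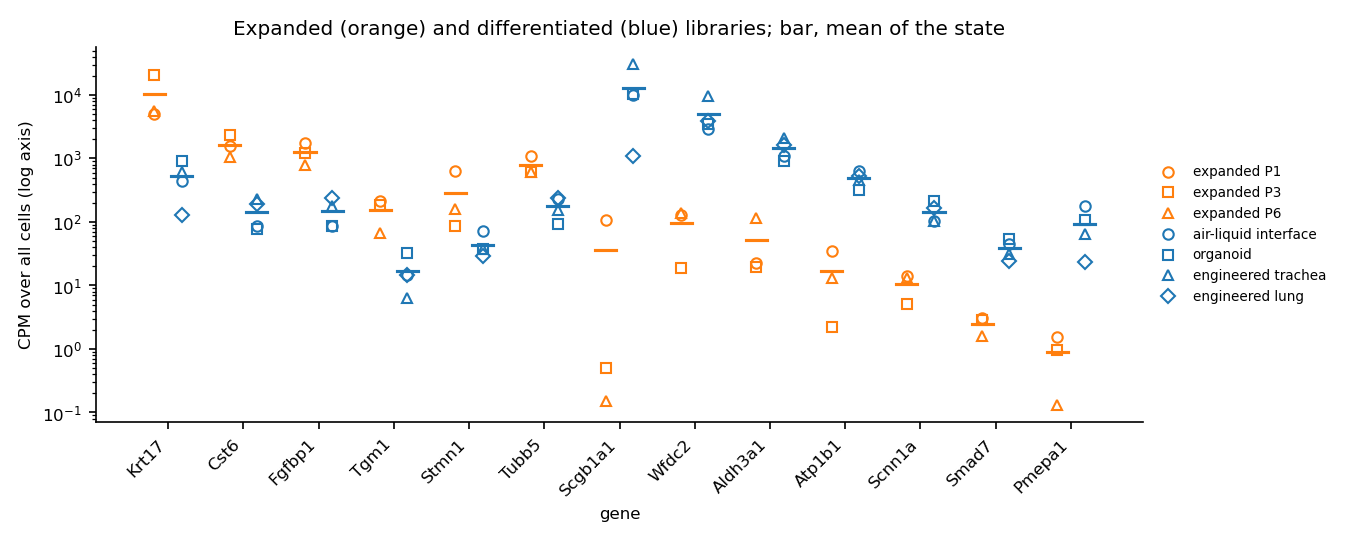
CPM over all cells (y axis, log scale) of 13 genes (x axis) in the 3 expanded (orange) and 4 differentiated (blue) libraries; bars are the mean of a state. Krt17 averages 10483 CPM in the expanded and 526 CPM in the differentiated libraries, and Smad7 2.52 and 38.9 CPM.

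Restricting the comparison to the basal class asked which differences were present within that class. Secretory genes rose there in 8 of 12 cases (11 adjusted over the list alone; median 5.21, camera adjusted p = 5.51e-10; adjusted p = 0.0976 with an estimated correlation). The naming rule had kept the P1 cluster led by secretory genes, 28.9% of P1 cells, out of the expanded basal class. Part of this difference is thus set by the rule. Over all cells, with that cluster included, the median was 5.60. Scgb1a1 went from 7.8 ± 13.1 to 1685 ± 890 CPM (adjusted p = 0.0452), a call that ended with any library but P1 left out, without the low-count filter and with the cell limits of the expanded libraries. Ciliated cells, which should lack it, held 3200 CPM at the air-liquid interface, 5201 CPM in the organoid and 12294 CPM in the engineered trachea, which exceeded the basal class of the same platform each time. BMP and TGF-beta feedback genes rose in 5 of 10 cases (6 adjusted over the list alone; median 2.12, camera adjusted p = 0.000133; adjusted p = 0.232 with an estimated correlation). Smad7 went from 2.45 ± 0.80 to 39.2 ± 10.7 CPM (3.66, SE 0.409, adjusted p = 0.00639) and Pmepa1 from 0.85 ± 0.66 to 92.1 ± 38.5 CPM (6.45, SE 0.806, adjusted p = 0.00918). Ion and water transport genes rose in 5 of 13 cases (8 adjusted over the list alone; median 2.99, camera adjusted p = 0.000136; adjusted p = 0.0976 with an estimated correlation), with the water channel Aqp4 at a log2 fold change of 9.49 (adjusted p = 0.00711). Xenobiotic metabolism genes rose in 6 of 18 cases (10 risen and 1 fallen adjusted over the list alone; median 3.0, camera adjusted p = 0.000574; adjusted p = 0.232 with an estimated correlation). They included Fmo2 (10.89, adjusted p = 0.00906) and the retinal dehydrogenase Aldh1a1 (6.28, adjusted p = 0.00906). Retinoid genes rose in 5 and fell in 1 of 12 cases (camera adjusted p = 0.00762; adjusted p = 0.221 with an estimated correlation), Rarres1 with a log2 fold change of 8.67 (SE 0.797, adjusted p = 0.00339). In the organoid Rarres1 stood at 96.2 CPM in basal, 245 CPM in ciliated and 311 CPM in secretory cells, and the basal class was the lowest of the 3 at the air-liquid interface and in the engineered trachea too. Interferon response genes rose in 3 of 16 cases (camera adjusted p = 0.00873; adjusted p = 0.26 with an estimated correlation). In the ciliary list 1 of 13 rose, Dynlrb2 (5 adjusted over the list alone; camera adjusted p = 0.00105; adjusted p = 0.389 with an estimated correlation). That call ended with any library but the engineered lung left out. The basal class of the engineered trachea held 35.6 CPM of Dynlrb2 against 5.38 CPM at the air-liquid interface, 1.82 CPM in the organoid and 1.02 CPM in the engineered lung. The engineered trachea also lay apart for the whole ciliary list, at a mean log2 (CPM + 5) of 4.33 against 2.91 to 3.13 on the other platforms.

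Among basal cells, respiratory chain genes fell in 2 of 11 cases (5 adjusted over the list alone; median -0.78, camera adjusted p = 0.000229; adjusted p = 0.26 with an estimated correlation) and cholesterol synthesis genes in 2 of 15, Fdps and Fdft1 (camera adjusted p = 0.0047; adjusted p = 0.542 with an estimated correlation). Library totals alone ended the calls of both lists, at medians of -0.41 and -0.46. Of 28 cell division genes 1 fell, Tubb5 (800 ± 264 to 302 ± 103 CPM, -1.79, adjusted p = 0.0252; list median -1.54, camera adjusted p = 0.00873; adjusted p = 0.651 with an estimated correlation). The ribosomal protein list had a median of -0.77 (camera adjusted p = 0.00185; adjusted p = 0.542 with an estimated correlation) with none of its 13 members called, and the cystatin and serpin list one of -1.28 (camera adjusted p = 0.00873; adjusted p = 0.287 with an estimated correlation). Library totals alone gave medians of -0.35 and -0.91. Cst6 fell from 1699 ± 594 to 144 ± 26.9 CPM (-3.94, SE 0.354, adjusted p = 0.00306) and Krt17 from 10191 ± 8086 to 1118 ± 651 CPM (-3.59, adjusted p = 0.0339). The cytokine gene Il24 fell from 401 ± 122 to 53.8 ± 43.8 CPM (-3.28, adjusted p = 0.0252), and Fabp5, Fgfbp1, Lypla1, Timm8a1, Mthfd2, Tmem97, Dnph1, Cdc42ep5 and Tgm1 fell as well. Vtcn1, an immune checkpoint ligand, rose from 0.23 ± 0.21 to 54.1 ± 13.4 CPM (7.57, SE 0.607, adjusted p = 0.00175), and the paraoxonase Pon3 from 0.24 ± 0.11 to 58.4 ± 32.9 CPM (7.55, SE 0.592, adjusted p = 0.00175). Fmo6, Bpifa5, Akr1cl, Sftpd, Ly6al, Abi3bp and Chst9 completed the named genes that rose. Of the named genes, Rarres1, Vtcn1, Pon3, Bpifa5, Akr1cl, Sftpd, Ly6al and Chst9 stood higher in the secretory than in the basal class of every platform, and Sftpd at the air-liquid interface was at 45.4 CPM in basal, 248 CPM in ciliated and 801 CPM in secretory cells. For these genes the comparison did not separate RNA made by basal cells from RNA carried over from secretory cells. The other 15 lists had camera adjusted p values from 0.0878 to 0.995. The basal marker list was among them (median -0.30, camera adjusted p = 0.341), and its median was 0.12 with library totals as the only scaling. Medians and tests differed in sign for the hypoxia list (median 0.07, camera direction down, adjusted p = 0.487) and the senescence and p53 list (0.12, down, adjusted p = 0.7). The edgeR test called 879 of 13262 genes, 537 risen and 342 fallen, and states did not overlap for 3693 of all tested genes, where chance gives 5.7%, 812 of them called. The count was 2697 with DESeq2, 471 with the cell limits of the expanded libraries and 56 without P3. Of 52 list members called, 8 passed with each library left out in turn. Scaling by library totals alone shifted the median of all genes by 0.379 and gave 1189 risen and 110 fallen.

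The passages were compared over all cells, and only P1 held a secretory-like cluster. Cell division genes, chemokines that recruit neutrophils and cholesterol synthesis genes were lower at P3 and lower again at P6, whereas basal keratins and squamous genes peaked at P3. These are differences between single libraries without a replicate check. From P1 to P3 the cell division list had a median log2 ratio of -2.32 (95% interval -2.35 to -2.26), with 27 of 28 members at least 2-fold lower. Mki67 stood at 63.6 CPM at P1, 8.73 CPM at P3 and 2.31 CPM at P6, and Top2a at 93.4, 13.5 and 3.2 CPM. At P6 the list's median against P1 was -3.10 (-3.15 to -3.03). Neutrophil-recruiting and antimicrobial genes had a median of -2.88 at P3 and -3.24 at P6, both against P1. Cxcl3 went from 6543 CPM at P1 to 127 CPM at P3 and 6.74 CPM at P6, and Cxcl1 from 808 to 34.7 and 5.66 CPM; both encode neutrophil chemoattractants. Cholesterol synthesis genes had medians of -0.98 at P3 and -1.48 at P6. Idi1, an isomerase of that pathway, stood at 493, 74.7 and 27.0 CPM. Mesenchymal transition genes had medians of -2.22 and -1.67 against P1.

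Basal markers had a median log2 ratio of 1.98 at P3 over P1 (1.96 to 2.00), with 7 of 10 members at least 2-fold higher, and of 0.63 at P6 over P1. Krt14 stood at 2458, 12373 and 3536 CPM over the 3 passages, and Krt17 at 5077, 20756 and 5616 CPM. Squamous genes had a median of 3.10 at P3 over P1 (3.07 to 3.14) and of -2.73 at P6 over P3. The small proline-rich gene Sprr1a stood at 7.98, 491 and 8.88 CPM, and the hillock keratin Krt13 was 98.7-fold higher at P3 than at P1. Among basal-like cells alone, without the squamous-like clusters, the squamous list still had a median of 2.64 at P3 over P1. Cystatin and serpin genes (1.73), dissociation and heat shock genes (1.21) and senescence and p53 genes (0.59) stood apart at P3 as well. Hspb1, a small heat shock protein, was at 141 CPM at P1 and 2467 CPM at P3, and the cell cycle inhibitor Cdkn2a at 3.99 and 178 CPM (44.6-fold, 39.6 to 50.4). The galectin Lgals7 showed the largest difference at P3 over P1, 2116 CPM against 7.0 CPM (302-fold, 277 to 331), followed by Dmkn, Cnfn, Ly6d, Sbsn and Krtdap. Il33, an alarmin, was 202-fold lower at P3 over all cells and stood at 712 CPM at P1 and 3.46 CPM at P3 among basal-like cells alone. Krt18, a simple epithelial keratin and a leading gene of the secretory-like P1 cluster, was 111-fold lower over all cells, and among basal-like cells stood at 29.2 and 1.07 CPM. At P6 over P1, Apoe stood at 463 against 2.15 CPM (216-fold) and Gpnmb at 187 against 8.94 CPM (20.9-fold). Fst, the activin antagonist, was lower at 1.30 against 408 CPM (315-fold), as was Csf3 at 0.58 against 195 CPM (335-fold). Scgb3a1 had 0 UMIs at P6 and was at least 3859-fold lower than at P1, where the secretory-like cluster held 717 CPM and basal-like cells 33.9 CPM.

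Between P3 and P6, keratinocyte stress and wound response genes had a median of -2.39, cystatin and serpin genes one of -1.43, dissociation and heat shock genes one of -1.17 and senescence and p53 genes one of -0.80. Ion and water transport genes were the list above the random range, at 0.66. Crip1 was 29.7-fold higher at P6 than at P3, Wfdc2 7.59-fold and Bst2 5.79-fold, while Serpinb2 was 18.1-fold and the protease inhibitor Slpi 118-fold lower. Keratinocyte stress genes also lay lower at P6 than at P1 (-1.96), and xenobiotic metabolism (0.80) and ribosomal protein genes (0.69) lay higher. At P3 over P1, xenobiotic metabolism (0.20) and laminin, collagen and integrin genes (0.14) stood slightly apart. TMM factors shifted the median of all genes by 0.36 for P3 over P1, 0.473 for P6 over P1 and 0.11 for P6 over P3, without turning the direction of any list that stood apart. Of 19 lists measured between P3 and P1, 11 stood apart, against 10 of 20 for P6 over P1 and 10 of 18 for P6 over P3.

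**Figure D3:**
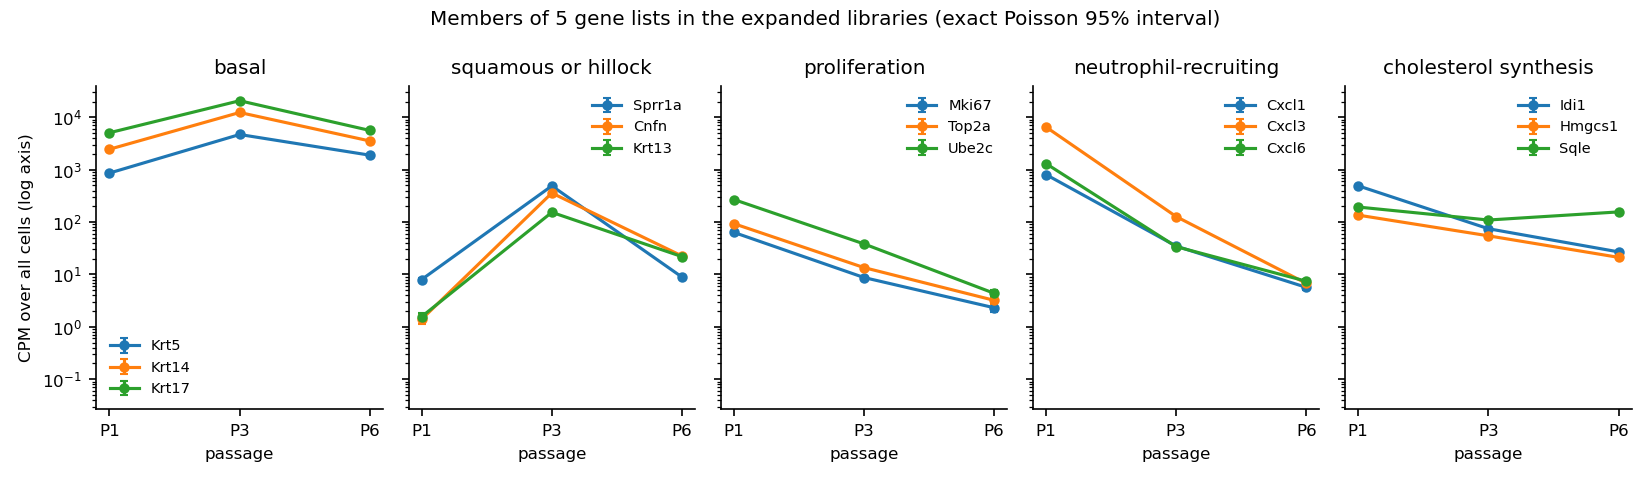
CPM over all cells (y axis, log scale) at P1, P3 and P6 (x axis) for members of 5 gene lists, with exact Poisson 95% intervals. Krt14 peaks at 12373 CPM at P3, while Mki67 runs from 63.6 CPM at P1 to 2.31 CPM at P6.

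Basal-like cells at P1 were set against native basal cells to describe how the 2 differed. Of the 640 native cells, 256 lay outside the cell limits of the expanded libraries. The comparison was not repeated under those limits. Neither the limits nor dissociation can be separated from entry into culture here. P1 cells had more transcripts of chemokines, cell division and cholesterol synthesis, and fewer of secretory, xenobiotic, antigen presentation and ion transport genes. Neutrophil-recruiting and antimicrobial genes had a median log2 ratio of 3.37 (3.11 to 3.64), with Cxcl3 at 7547 against 1.95 CPM (3873-fold, 2040 to 8470) and Cxcl1 at 964 against 22.3 CPM (43.2-fold). Cell division genes had a median of 3.2 (3.08 to 3.34), with 26 of 28 members at least 2-fold higher; Ube2c was 91.9-fold and Cdkn3 186-fold higher. Cholesterol synthesis genes had a median of 2.09 with 14 of 15 at least 2-fold higher, and keratinocyte stress genes (2.10) and hypoxia and glycolysis genes (1.23) also lay above the random range. Krt7, a keratin of simple and cultured epithelia, stood at 1890 against 26.2 CPM (72.1-fold, 60.4 to 86.9). Fam25a had 0 UMIs in native basal cells and was at least 1136-fold higher at P1. Il24 had 2 UMIs there against 23719 (ratio 1168, 323 to 9646).

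Secretory genes had a median of -6.01 in P1 basal-like cells against native basal cells, where all 11 were at least 2-fold lower. The naming rule had kept the secretory-like cluster out of the P1 class, which sets part of this difference. Scgb1a1 stood at 23.0 against 8125 CPM, but native ciliated cells, which should lack it, held 28276 CPM, more than the native basal cells. Medians were -3.09 for xenobiotic metabolism, -2.72 for antigen presentation, -2.44 for ion and water transport, -1.98 for retinoid, -1.68 for BMP and TGF-beta response, -1.5 for alveolar and -1.46 for interferon response genes. Immediate early and heat shock genes lay lower (-3.83), with Fos at 17.8 against 2535 CPM (142-fold). The phospholipase gene Pla2g4c was 4214-fold lower at P1, and Calml3 537-fold. Clca1 (3 against 5100 UMIs), Bpifa1, Bpifa5, Csap1, Cyp2f4 and Wfdc2, genes of secretory cells or glands, were lower too. Krt5 stood at 1109 CPM at P1 and 1010 CPM in native basal cells, and the basal list's median was 0.01. TMM factors moved the median of all genes by 0.395, and 14 of 24 lists stood apart.

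Platforms were then compared with native trachea class by class, to see how closely each came to the tissue. All of these ratios share the native library, so a direction seen on several platforms is not independent evidence of a shared effect. Among basal cells, genes of antigen presentation had medians of -2.55 at the air-liquid interface, -2.78 in the organoid, -2.71 in the engineered trachea and -2.64 in the engineered lung. The invariant chain Cd74 stood at 1.53 CPM in the engineered lung against 320 CPM in native basal cells. Hypoxia and glycolysis genes were highest in the engineered lung, with a median of 2.41 (2.30 to 2.62) and 20 of 21 members at least 2-fold higher, against 1.07 in the engineered trachea, 0.78 in the organoid and 0.35 at the air-liquid interface. The stress gene Ndrg1 stood at 1382 CPM in the engineered lung, 318 CPM in the engineered trachea and 10.4 CPM in native basal cells. Of the 272 engineered lung basal cells, 132 were named Tp63BasalLike, a subset with no basal marker among its 10 leading genes against all other cells, which included Ndufa4l2, Plod2 and Car9. Against cells outside the basal class it had 2, Col17a1 and Krt17, and 9 basal markers reached 50 CPM in it. Ndrg1 stood at 2309 CPM in that subset and at 557 CPM in the other, Krt5BasalLike. Car9 and Egln3, both induced by low oxygen, had 2 and 3 UMIs in native basal cells and 196 and 214 CPM in the engineered lung. Keratinocyte stress genes were highest in the organoid (3.38, 3.15 to 3.62), where the growth factor Areg was 80.8-fold and the urokinase receptor Plaur 43.4-fold higher than in native basal cells. The neutrophil-recruiting and antimicrobial list had medians of 0.98, 2.33, 2.75 and 1.28 in the order air-liquid interface, organoid, engineered trachea and engineered lung. Its chemokines Cxcl1 and Ccl20 were lower in the engineered lung than in native basal cells, at 8.16 against 22.3 CPM and 2.38 against 141 CPM. Lcn2, an iron-binding antimicrobial protein, stood at 266 CPM at the air-liquid interface and 358 CPM in the engineered trachea against 1.95 CPM. Krt7 was 27.0-fold, 38.8-fold, 47.7-fold and 76.7-fold higher in the same order.

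Cell division genes lay above native basal cells at the air-liquid interface (1.44), in the engineered trachea (1.14) and in the engineered lung (1.61). Cholesterol synthesis genes had medians of 0.51, 0.56, 1.17 and 1.41 in the order given, senescence and p53 genes 0.69, 0.97, 0.79 and 1.27, and laminin, collagen and integrin genes 0.66, 0.89, 0.38 and 0.77. YAP targets stood apart at the air-liquid interface (0.79) and in the organoid (1.31), where the matricellular gene Ctgf was 49.0-fold and 75-fold higher than in native basal cells. Mesenchymal transition genes stood apart at the air-liquid interface (1.11), in the organoid (1.36) and in the engineered lung (1.15). Squamous genes were higher in the engineered lung (1.71) and at the air-liquid interface (0.51) and lower in the organoid (-1.02). Secretory genes had medians of -3.2, -2.11, -2.18 and -3.24, and dissociation and heat shock genes -2.41, -2.07, -1.5 and -1.5. Native ciliated cells, which should lack Scgb1a1, held more of it than the native basal cells used as reference here. Secretory RNA carried over into the native basal class was thus not separated from a lower level on the platforms. Ion and water transport genes lay lower in the organoid (-1.13), engineered trachea (-0.90) and engineered lung (-0.85). Interferon response genes lay lower at the air-liquid interface (-0.48), in the organoid (-0.81) and in the engineered trachea (-0.54). Xenobiotic metabolism genes went opposite ways, at 0.65 for the air-liquid interface and -0.80 for the engineered lung. Retinoid genes lay higher in the engineered lung (0.71), with Rbp2 at 203 against 0.87 CPM, and lower in the organoid (-1.06). Of the lists measured, 19 of 25 stood apart at the air-liquid interface, 16 of 25 in the organoid, 13 of 25 in the engineered trachea and 16 of 24 in the engineered lung. TMM factors shifted the median of all genes by 0.399 for the organoid, 0.187 for the engineered trachea and 0.151 for the engineered lung.

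In the secretory class, native cells devoted 260720 CPM to Scgb3a1 and 102781 CPM to Csap1. The native subset named CD66+Secretory, 62 of the 174 cells and led by Csap1, Lipf and Scgb3a1, held 411371 CPM of Scgb3a1, and the other subset, Scgb3a1+Secretory, 19427 CPM. Against the whole class, the median gene lay above native by 0.64 at the air-liquid interface, 0.515 in the organoid, 0.494 in the engineered trachea and 0.56 in the engineered lung. TMM factors moved those medians by -0.499, -0.283, -0.308 and -0.443. Relative to random lists, secretory genes were lower everywhere, with medians of -1.88, -1.81, -1.27 and -3.06 in that order. Scgb3a1 stood at 293 CPM at the air-liquid interface, 1317 CPM in the organoid, 1471 CPM in the engineered trachea and 5.36 CPM in the engineered lung, below both native subsets; CD66+Secretory cells dominated the difference from the whole native class. Hypoxia and glycolysis genes again stood highest in the engineered lung, with a median of 3.50 (3.28 to 3.62) and all 21 members at least 2-fold higher; Ndrg1 was 440-fold higher there (291 to 703). Of the 345 secretory cells of the engineered lung, 241 were named Ceacam1Secretory, a subset with no secretory marker among its leading genes against all other cells, which included Ndrg1 and Ero1a. Against cells outside the secretory class it had 1, Agr2. Ndrg1 stood at 2390 CPM in that subset and at 361 CPM in cells named Secretory. The engineered trachea subset named Intermediate also had no secretory marker among its leading genes against all other cells, and 1, Scgb1a1, against cells outside the class. Keratinocyte stress genes had medians of 5.18 in the organoid, 3.37 in the engineered trachea and 2.77 in the engineered lung, and Plaur was 263-fold higher in the organoid. Against all other cells of their library, the organoid subsets named Ceacam1 and HopxSecretory had no secretory marker among their 10 leading genes. Against cells outside the class, HopxSecretory had 3. The organoid subset named Secretory1 alone gave 5.48 for keratinocyte stress genes, -1.70 for secretory genes, 2.66 for YAP targets and 1.95 for senescence and p53 genes. Laminin, collagen and integrin genes had medians of 1.25, 2.29, 2.29 and 1.66, senescence and p53 genes 1.5, 2.26, 2.28 and 2.65, and neutrophil-recruiting and antimicrobial genes 2.47, 2.13, 2.46 and 1.43. Cxcl1, of the latter list, stood at 1.53 CPM in the engineered lung against 6.38 CPM in native secretory cells. Lcn2 was 59.0-fold higher at the air-liquid interface. YAP targets stood apart at the air-liquid interface (1.70), in the organoid (2.98) and in the engineered trachea (1.44), with Ctgf 343-fold and 654-fold higher in the former pair. Antigen presentation genes had medians of -0.42, -2.28, -2.22 and -2.16. The aldehyde dehydrogenase Aldh3a1 stood at 2242 CPM in the engineered trachea and 1984 CPM in the engineered lung against 34.5 CPM, and Mal was 1978-fold higher in the engineered lung. Mal and the stress list gene Serpinb2 were among the leading genes of native cells named Keratinocyte. Those cells were counted as basal, and the secretory ratios were not computed with them included. Notch genes stood apart at the air-liquid interface (1.53) and in the engineered trachea (1.95), cell division genes were lower in the organoid (-1.56), and squamous genes were higher in the engineered lung (2.56). The low positive medians of the basal list at the air-liquid interface (0.23) and of the respiratory chain list in the engineered lung (0.23) lay below the random range and turned negative with TMM factors (-0.41 and -0.312). The dissociation list of the engineered trachea (0.41) likewise turned to -0.172 with the mean over cells. Lists that stood apart numbered 13 of 21, 11 of 22, 15 of 23 and 14 of 23 in the order given.

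Ciliated cells were compared for the 3 platforms that held them. Their own marker list differed little from native at the air-liquid interface (-0.21) and in the engineered trachea (0.29), both inside the random range, and was lower in the organoid (-1.23, -1.39 to -1.06), where 12 of 19 members were at least 2-fold lower. The neutrophil-recruiting and antimicrobial list was higher on each platform, with medians of 2.08 at the air-liquid interface, 3.12 in the organoid and 2.15 in the engineered trachea. Lcn2 was 442-fold higher at the air-liquid interface and 120-fold in the engineered trachea, and Cxcl1 244-fold higher in the organoid. Keratinocyte stress genes had medians of 1.80, 3.96 and 2.00, YAP targets 1.19, 1.52 and 0.87, and antigen presentation genes -1.67, -2.67 and -2.88. Tuft genes lay lower at -2.42, -3.2 and -3.46, and the tuft kinase Dclk1 stood at 331 CPM in native ciliated cells, which should lack it. Cholesterol synthesis genes were higher at the air-liquid interface (0.89) and in the engineered trachea (1.39), and ribosomal protein genes were lower in the engineered trachea (-1.11). Resp18, a neuroendocrine gene, stood at 560 CPM in engineered trachea ciliated cells against 2 UMIs in native ones (ratio 361, 99.8 to 2983), and the chitinase Chia was 45.5-fold higher there. Chia and Lcn2 were among the leading genes of the engineered trachea secretory subset named Scgb3a2+, against all other cells. Ciliated cells held 12294 CPM of Scgb1a1 there and 3200 CPM at the air-liquid interface. For these genes and the antimicrobial list, RNA made by ciliated cells was not separated from RNA carried over from secretory cells. Hbb, of red blood cells, was counted as 0 on the platforms and stood at 2417 CPM in native ciliated cells. Lists that stood apart numbered 13 of 24, 15 of 26 and 13 of 24, and TMM factors shifted the median of all genes by 0.134 for the organoid.

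**Figure D4:**
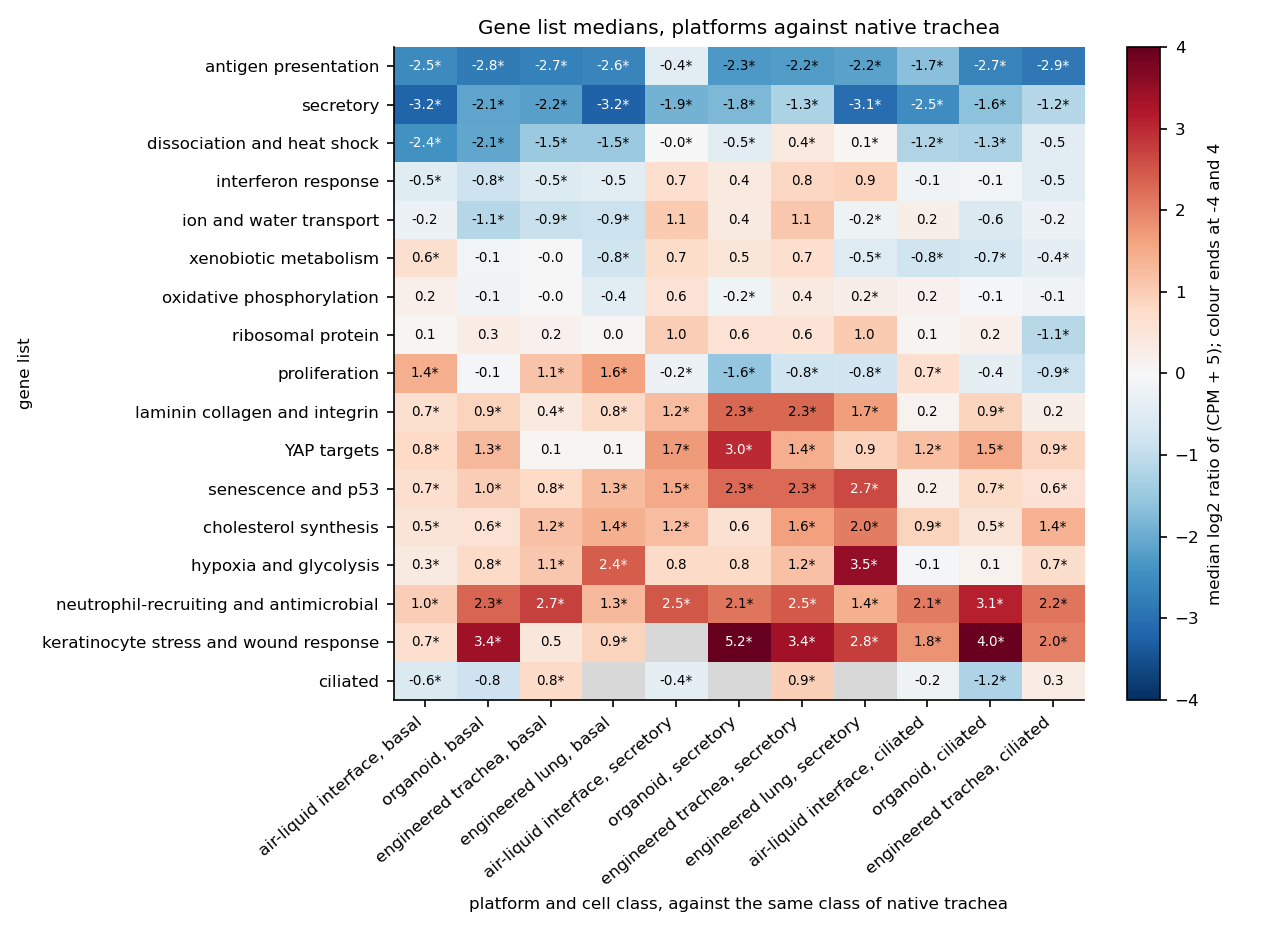
Median log2 ratio of (CPM + 5) of 17 gene lists (y axis) in each platform and class (x axis) against the same class of native trachea; asterisks mark lists outside the middle 95% of random lists, and grey marks lists with too few measured members. Hypoxia and glycolysis reaches 2.41 and 3.50 in engineered lung basal and secretory cells, and keratinocyte stress 5.18 in organoid secretory cells.

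Each platform was also set against the other 3 over all cells. Il33 stood highest at the air-liquid interface, at 629 CPM and 9.32-fold over the next platform, where Wfdc1, Cdh6 and Col8a1 were also highest. Hopx, of the alveolar list but also a leading gene of the squamous-like P6 cluster, was lowest there at 5.44 CPM. It was highest in the engineered lung at 1255 CPM. The organoid led in the epidermal growth factor receptor ligand Ereg (152 CPM, 11.9-fold over the next), in the neuregulin Nrg1 (1211 CPM, 5.94-fold) and in Cxcl1 (967 CPM, 5.43-fold). Fos was lowest in the organoid at 47.8 CPM. The engineered trachea led in Resp18 (58.6 CPM, 51.5-fold), Grik2 (515 CPM, 7.75-fold) and Depp1 (1070 CPM, 6.03-fold), and had the lowest Krt5 at 214 CPM. It also had the lowest share of basal cells (20.7%), and in its basal class Krt5 stood at 1024 CPM, against 1174 to 1871 CPM on the other platforms. In the engineered lung, Gpha2 stood at 335 CPM (122-fold over the next), Ndufa4l2 at 245 CPM (86.2-fold), Cda at 575 CPM (16.1-fold) and Prss27 at 94.1 CPM. Bpifa1, an antimicrobial protein of the upper airway, was lowest in the engineered lung at 146 CPM, against 22843 CPM at the air-liquid interface, 57950 CPM in the organoid and 34892 CPM in the engineered trachea. Scgb3a1 (4.12 CPM), Akr1cl (1.83 CPM) and Gstm1 (22.4 CPM) were lowest there too. Among basal cells the oxidoreductase Ero1a stood at 1152 CPM in the engineered lung, 12.9-fold over the engineered trachea.

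Whole profiles were compared with native trachea by correlation across genes, which are not independent replicates. For basal cells, Spearman's rho was 0.485 at P1, 0.541 at P3 and 0.557 at P6, then 0.631 in the engineered lung, 0.640 in the organoid, 0.724 in the engineered trachea and 0.740 at the air-liquid interface. For secretory cells it was 0.438 for the secretory-like cluster at P1, 0.539 in the organoid, 0.551 in the engineered lung, 0.653 in the engineered trachea and 0.696 at the air-liquid interface. Native CD66+Secretory cells gave 3088038 of the 5016044 UMIs of the native secretory profile. Similarity to the other native secretory subset alone was not computed. In ciliated cells rho was 0.635 in the organoid, 0.720 at the air-liquid interface (0.716 to 0.724 over 20 draws of UMIs) and 0.722 in the engineered trachea (0.719 to 0.724). The order of the latter pair turned with Pearson's correlation, with genes of at least 100 CPM and with called doublets left out. Sums were thinned to 4618955, 5016044 and 656214 UMIs for the 3 classes.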

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

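The tests of the 3 patterns weighed here were written down before their outcome was computed, except the one on cell limits, which was chosen after the cells per library had been seen.

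Among 54 values compared between libraries of 1 state, 2 lay apart by Dixon's ratio, a number that chance at about 1 in 20 per value could give. Laminin, collagen and integrin genes averaged a log2 (CPM + 5) of 6.86 over all organoid cells, against 5.93 to 6.04 on the other platforms, with a Dixon ratio of 0.886. Organoids are grown in matrigel and dissociated in their own way, which was not tested. They also had the largest basal share of the platforms, 50.36% against 20.74% to 37.8%. The list shares Col17a1, Itga6 and Itgb4 with the basal markers, and within the basal class it was not flagged. A difference in cell composition was not separated from these factors. Ciliary genes averaged 4.33 in the basal class of the engineered trachea, against 2.91 to 3.13 on the other platforms, with a ratio of 0.846, and no test was made of its source.

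Secretory transcripts in the basal class of the platforms may be basal expression or may come from 1 outside source, such as free RNA, doublets or misnamed cells. A single source would keep the ratio of basal to secretory CPM alike over genes within a platform. Its highest and lowest value differed 10.11-fold at the air-liquid interface, 6.49-fold in the engineered trachea, 2.07-fold in the engineered lung and 1.51-fold in the organoid. The spread at the air-liquid interface rested on Muc5b, at 56.18% of its secretory level and only 6.79 against 12.09 CPM, while the other genes there ran from 5.56% to 25.91%. With the lowest spread at 1.51, the values leave the source open. Lypd2 drove the spread in the engineered trachea, at 44.55% of its secretory level against 6.87% for Scgb1a1.

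Grouping by chance could produce differences between expanded and differentiated libraries. Of 35 ways to split the 7 libraries into 3 and 4, only 1, the real split, called as many genes as 3312, and the highest other split called 2. In the basal class the real split, again 1 of 35, called 879 genes and the highest other 3. Every other split mixes the states, so a large difference between them widens the spread within its groups and keeps its count low. The real split counts itself, so 1 of 35 is also the lowest possible outcome. The test therefore says little about grouping by chance. Limits on cells before deposit could also contribute. With the limits of the expanded libraries in every library, 3032 of the 3312 called genes still had a value. Those 3032 kept 81.1% of their log2 fold change at the median (quartiles 70.6 to 92.9), just past the 80 set as the bound. The other called genes are left out of this figure, and a part of the sizes may still come from cell selection.

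The lower cell division genes at P6 might reflect the limit of 4500 genes per cell removing cycling cells. Cycling cells at P3 had 1.079 times the genes of other cells, and this ratio times the P6 median gave 3904.6 genes, under the 4000 set beforehand as the bound against this explanation. That median came from cells already under the limit, which was recognised only after the outcome was seen, so a product below the limit decides nothing. P6 cells with 4000 or more genes had 925.8 CPM of these genes against 896.6 CPM in all P6 cells and 4153.1 CPM at P1. Cells above the limit were not analysed here, which leaves this explanation open.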

How the results depend on the processing

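Most alternatives were planned, and 8 were chosen after seeing data: the cell limits, the top doublet scores, the other annotation column and the subset restrictions. Of 238 main results under an alternative, 212 stayed on the same side and within range, 25 moved and 1 was lost. Of 5483 values of single genes, 901 lost their call, 446 moved and none reversed. The stricter cell filter left out 148 air-liquid interface cells and 0 cells of every other library. Called doublets were 1 (P3) to 20 (P6) cells per library. These settings could hardly change a result, so the numbers that stayed the same, here and for lists, say little about robustness. The count of called genes over all cells, 3312, was 5012 with DESeq2 and 796 with the cell limits of the expanded libraries, which tested fewer cells and genes. Leaving out 1 library gave 490 (P3) to 2914 (engineered lung), with 1404 without the engineered trachea, 1646 without the organoid, 1696 without P1, 1777 without the air-liquid interface and 2063 without P6. For the basal class, 879 became 2697 with DESeq2, 471 with the cell limits, and 56 (P3) to 596 (P6) with 1 library left out, with 132 without the engineered trachea, 251 without the organoid, 355 without P1, 399 without the engineered lung and 454 without the air-liquid interface. No called gene turned direction. Of 17 lists called by camera, 0 were called with an estimated correlation, where the lowest adjusted p was 0.229 and the highest 0.935. Fry asks whether a list's members change in a common direction, without comparing them with other genes. It called 14 lists, 12 of them shared with camera. The ciliary (fry adjusted p = 0.0914), cell division (0.102), squamous (0.0738), basal (0.0983) and cholesterol lists (0.122) were not called by fry. With the other native annotation, basal cells were 42.97% and secretory cells 33.91%. Similarity to native at the air-liquid interface was 0.828 by Pearson's correlation and 0.601 over genes with at least 100 CPM for basal cells, and 0.779 and 0.604 for secretory cells; for ciliated cells of the engineered trachea it was 0.789, 0.581 and, without thinning, 0.742.

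Of 1756 list results, 1186 stayed the same, 539 moved, 22 became weaker, 2 became stronger and 7 reversed, the last all in the secretory class against native cells. The basal list at the air-liquid interface was -0.41 with TMM factors and -0.102 without native CD66+Secretory cells. The dissociation and heat shock list of the engineered trachea was -0.172 with the mean over cells and -0.457 without those cells. The oxidative phosphorylation list of the engineered lung was -0.11 with the mean over cells, -0.312 with TMM factors and -0.311 without those cells. Native secretory totals are dominated by few genes, so these ratios move with the scaling; for other changed results the cause was not tested. No paired analysis was possible because the labels name no shared animal or culture.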

Other observations

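Named subsets inside the classes differed widely. In native trachea, cells named CD66+Secretory, 62 of 640, devoted 411371 CPM to Scgb3a1, against 19427 CPM in the other secretory subset, Scgb3a1+Secretory. Native Tuft2 cells held 91.7 CPM of the neuropeptide gene Calca and 37.3 CPM of Resp18, against 8.71 and 5.44 CPM in Tuft1 cells. Bpifa1, a secreted antimicrobial, stood at 119545 CPM in organoid Secretory1 cells and 76811 CPM in engineered trachea Scgb3a2+ cells. In the engineered lung, cells named Bpifa1Secretory held 286 CPM of Bpifa1, less than the 1147 CPM of those named Secretory.

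The engineered trachea held a cluster named Foxn4, 33 of 2613 cells, with the centriole amplification genes Ccno at 512 CPM and Deup1 at 417 CPM, against 7.77 and 41.6 CPM in its ciliated cells. Resp18 reached 559.8 CPM in those ciliated cells, 30.5 CPM in organoid ciliated cells and 1.46 CPM in air-liquid interface ciliated cells. At the air-liquid interface, 99 cells named EMT held 1204 CPM of Fn1 and 1242 CPM of Tagln. Hopx stood at 4827 CPM in the engineered lung class of that name, and at 2526 and 2147 CPM in the squamous-like clusters of P3 and P6. The hillock keratin Krt13 stood at 294.5 CPM in that lung class, and at 693 and 329 CPM in those clusters. Surfactant Sftpc was found in each engineered lung cluster, at 13.8 to 39.9 CPM, and free RNA was not tested as its source.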
